A study of Mus musculus with 10 samples.

How the data were processed

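Gene expression was measured on 10 Affymetrix arrays hybridised with RNA of mouse Sertoli cells, the supporting cells of the seminiferous tubule. The samples formed 5 groups of 2 arrays: cells of mice aged 6 days post partum (dpp) treated with 0, 5 or 50 ng activin, and cells of mice aged 15 dpp treated with 0 or 5 ng activin. The labels give the dose in ng without a volume, and nothing in the sources used here says whether the 2 replicates of a group came from separate animals or preparations, so the p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, total RNA was isolated with Trizol, copied by one-cycle 3' amplification and labelled with biotin.

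The deposited values were 1 linear intensity (a probe set signal) per probe set and array, for 45101 probe sets, as processed by the authors. The values ran from 0.024 to 10734, and the mean without the lowest and highest 2% of probe sets was 125.001 on each of the 10 arrays, so each array had been scaled to a common trimmed mean. The summarisation software and the scaling method are not given in the sources used here. No column of values was left unused (0 columns). Arrays carry no count depth; the number of arrays, 2 per group, limits the precision.

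From these values, 64 control probe sets were left out, which left 45037. Signals were turned into log2(signal + 16) and quantile normalised. A log2 change on this scale understates the change of genes with low signals. Probe sets whose mean lay under the 40th percentile, a log2 level of 5.10 or a signal of 18.4, were dropped, which left 27022. Gene symbols came from the platform's annotation of 2016, updated through the RefSeq gene table of assembly GRCm38.p6 by gene identifier. Of the probe sets used, 34945 had 1 gene symbol, 932 had several and 9160 had none; of those with 1 symbol, 34741 were matched to a current symbol and 204 kept the annotation's name. Probe sets with several or no symbols were not named. Each gene was represented by its probe set with the highest mean over all arrays, which gave 12405 genes, of which 5934 had several probe sets. Some genes of the lists below were not analysed here.

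All 5 groups were fitted in 1 linear model per gene with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), which left 5 residual degrees of freedom before moderation. The 6 comparisons were 5 ng against 0 ng at 6 dpp, 50 ng against 0 ng at 6 dpp, 50 ng against 5 ng at 6 dpp, 5 ng against 0 ng at 15 dpp, 15 dpp against 6 dpp at 0 ng, and the difference of the 5 ng response between the ages. P-values are two-sided and were adjusted by Benjamini-Hochberg within each comparison; a gene passed with an adjusted p under 0.05, with no minimum fold change. Every adjusted p of a single gene printed below is from limma. Values are given as the log2 change ± its standard error (SE) and as the mean deposited signal ± SD over the 2 arrays of a group.

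The 22 gene lists were written before the data were examined, as were the groups, the tests, the rule for named genes and all alternatives except the replicate block within each age. The 21 lists with at least 5 measured genes were tested with limma's camera, which compares a list with the other genes, at a preset correlation between genes of 0.01, and adjusted over all 126 tests. Because the preset can be too low, the test was repeated with the correlation estimated for each list. The fry test, which asks whether the genes of a list move on balance one way without comparing them with other genes, was run beside it. Lists overlap; for example, 6 genes are shared by the matrix and fibroblast lists and 7 by the junction and Sertoli cell maturation lists.

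Named genes are, in each comparison, up to 8 with the largest positive and 8 with the largest negative change among genes that passed and whose arrays did not overlap between the groups; the 5 genes with the smallest p where fewer than 5 passed; Inhba, Inhbb, Inha, Fst, Smad2, Smad3, Smad7, Skil, Ccnd2, Gja1, Serpina5 and Amh throughout; and up to 4 genes with the smallest p in each list described. For the difference between the ages in the response, the numbers were 5 and 5. Clone names were passed over, and other genes are said to have been chosen after their values were seen.

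The changes at 5 and 50 ng at 6 dpp share their 0 ng arrays, so their agreement was set beside 100 simulations. In these, unchanged groups shared a simulated control group, and each array was drawn independently from the fitted spread of each gene. The fits were tested on simulated data with 200 changed genes among 12405 in 10 draws. For 50 ng against 0 ng at 6 dpp, 48.5% of changes of 0.5, 93.3% of changes of 1 and 100% of changes of 2 on the log2 scale were recovered, and 6.77% of the calls were false. Each array was drawn independently from the fitted spread, without ties between arrays of the same number, and the changed genes were divided about equally among the sizes. The shares recovered hold under these settings and may be too high for the arrays themselves. Camera called a simulated list of 20 genes raised by 0.5 in 100% of 50 draws. These calls were made at an unadjusted p under 0.05, a laxer threshold than the adjusted p used for the lists. Lists that passed in the activin comparisons shifted less. Their largest mean in size was -0.27, for cholesterol synthesis genes at 50 ng and 6 dpp, with an estimated correlation between genes of 0.406. The simulated list therefore does not show how often camera finds shifts as small as those reported, or how it performs on genes correlated that strongly. The difference of the response between the ages was not simulated. The alternatives changed 1 choice at a time: the normalisation, the pseudocount, the filter, the handling of several probe sets, the moderation of the variance, the arrays in the fit, the replicate number as a block, the family for adjustment, the correlation between list genes, and leaving out each array in turn.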

Results

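Mouse Sertoli cells of 2 ages were profiled after treatment with activin, a TGF-beta family ligand that signals through SMAD2 and SMAD3. The design asked how the response to activin depends on dose at 6 dpp and on age between 6 and 15 dpp; the labels name the developmentally regulated use of the 2 SMAD proteins as the subject. Each of the 5 groups held 2 arrays, and n = 2 applies to every mean signal below. Median signals ran from 29.7 to 35.3 across the 10 arrays, and 58.1% to 63.0% of probe sets lay above the filter's signal.

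Age separated the arrays far more than dose. The first principal component held 88.0% of the variance and split 6 from 15 dpp, and the second held 2.49%. Correlations across genes lay between 0.987 and 0.990 within a group, between 0.982 and 0.991 for different doses at the same age, and between 0.827 and 0.852 for different ages. No pair of arrays shared more than 0.0044% identical signals.

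At 6 dpp, 50 ng activin raised Hsd17b1, Serpina5, Socs2 and Hsd17b3 and lowered Rarres1, among 179 genes that passed. Hsd17b1, which reduces estrone to estradiol, rose by 1.90 ± 0.17 on the log2 scale, from a signal of 71.0 ± 2.7 to 307 ± 44 (adjusted p = 0.00045). Serpina5, the protein C inhibitor, rose by 1.27 ± 0.15, from 283 ± 20.1 to 708 ± 43 (adjusted p = 0.0030), and Socs2, a suppressor of cytokine signalling, by 1.30 ± 0.18, from 329 ± 47 to 839.9 ± 159.9 (adjusted p = 0.0064). Hsd17b3, which converts androstenedione to testosterone, rose by 1.19 ± 0.21, from 339.9 ± 69.96 to 798 ± 148 (adjusted p = 0.017). Rarres1, a retinoic acid receptor responder, fell by 1.25 ± 0.12, from 266 ± 2.4 to 104 ± 6.6 (adjusted p = 0.00080).

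The other genes with the largest increases at 50 ng were E2f5 (log2 change 1.86), Zg16 (1.77), the sodium-dicarboxylate cotransporter Slc13a2 (1.70), the homeobox gene Prrx2 (1.46) and the calcium-binding protein gene Tesc (1.30). The 3 probe sets of E2f5 disagreed, as described for the 5 ng dose. The largest decreases also included Parvb, a focal adhesion protein gene (-1.47), Il10ra (-1.43), Ctdspl2 (-1.18), Acp5, which encodes tartrate-resistant acid phosphatase (-1.18), the phospholipase gene Plcd3 (-1.09), Ccdc74a (-1.01) and Mgarp (-0.92). Signals of Il10ra, Acp5, Plcd3 and Ccdc74a were low, between 29.5 and 37.4 at 0 ng, and 1 of the 4 probe sets of Ccdc74a moved the other way. Slc13a2 had a signal of 6.40 ± 5.5 at 0 ng, under the filter's 18.4, and its change ran from 0.78 to 3.13 over the alternatives. Parvb lay at 9.51 and Il10ra at 2.14 at 50 ng. The sizes of low genes, and so their rank, depended on the processing, with ranges of -3.51 to -0.55 for Il10ra, -2.55 to -0.67 for Parvb, -2.53 to -0.46 for Acp5, -1.95 to -0.47 for Plcd3 and -1.86 to -0.34 for Ccdc74a.

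In all, 179 genes (1.44%) passed at 50 ng, 97 higher and 82 lower, with 17 higher and 7 lower by more than 2-fold. At an unadjusted p under 0.05, 1739 genes differed, where chance gives 620.25. Hsd17b1, Serpina5, Rarres1 and Prrx2 passed under every alternative in which they were measured. The count fell to 98 with array medians subtracted, 110 without the filter, 46 without the variance trend and 94 with only the 4 arrays of the comparison. It fell to 60 without 0 ng replicate 1, to 17 without 0 ng replicate 2, to 115 without 50 ng replicate 1 and to 17 without 50 ng replicate 2, and all 179 genes kept their sign in each of these 4 fits. Of the other genes named above, Socs2 missed the threshold without 50 ng replicate 2 (adjusted p = 0.071) and Hsd17b3 without that array or either 0 ng replicate (adjusted p up to 0.16). The remaining calls ended without at least 1 of these arrays, with adjusted p values over all alternatives of up to 0.42, for Ccdc74a.

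**Figure D1:**
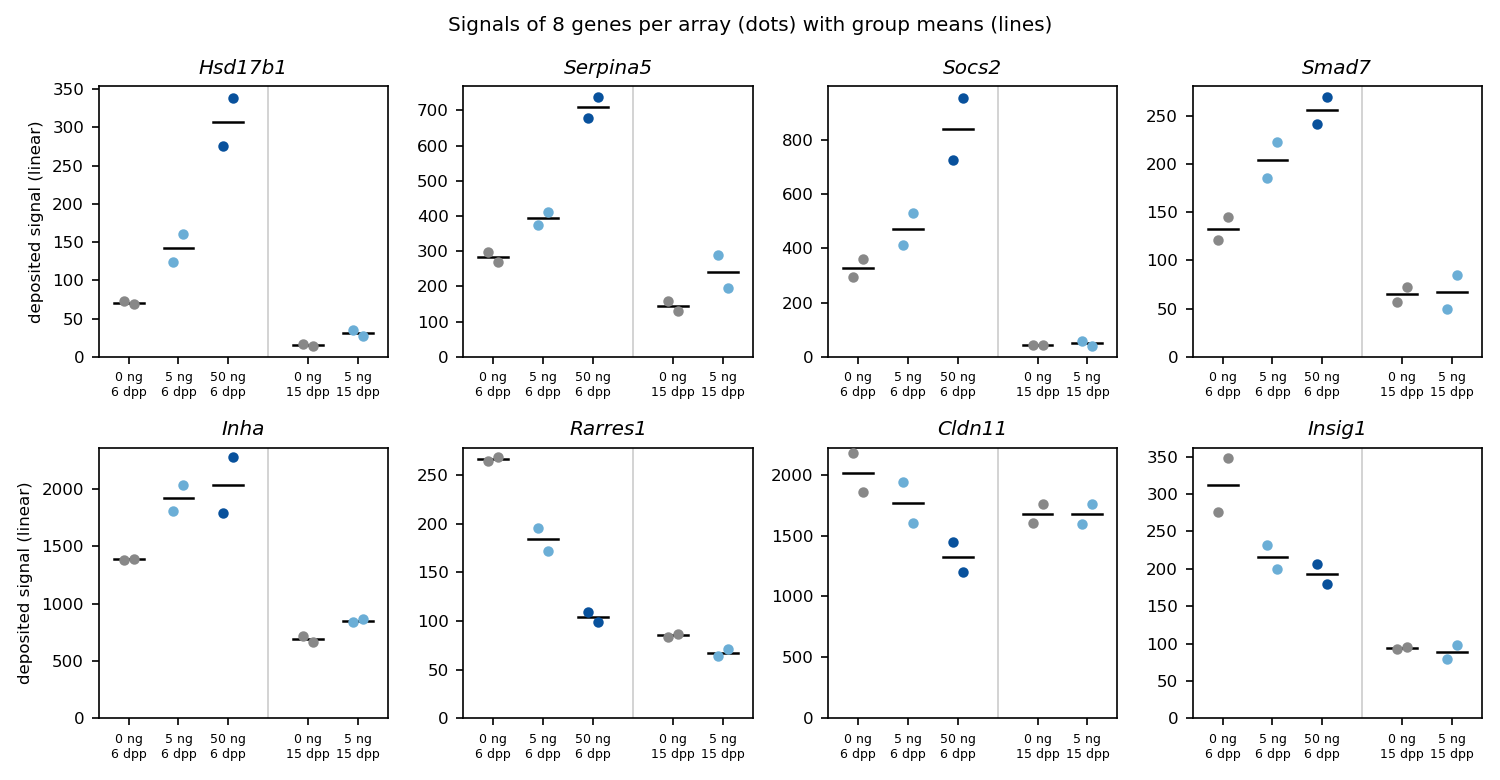
Deposited linear signals of 8 genes on each of the 10 arrays (dots; lines are the means of 2 arrays), by activin dose and age, each vertical axis starting at 0. Hsd17b1 had mean signals of 71.0, 142 and 307 at 0, 5 and 50 ng at 6 dpp, Rarres1 266, 184 and 104, and Socs2 lay at 42.7 and 50.3 at 15 dpp.

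Among the 26 measured SMAD2/3 target and feedback genes, 2 rose at 50 ng and none fell; adjusted over the list alone, 5 rose and 2 fell. Fstl3, which binds and neutralises activin, rose by 1.11 ± 0.16, from 159.9 ± 37.9 to 356 ± 37 (adjusted p = 0.0077), and Smad7, an inhibitory SMAD, by 0.88 ± 0.19, from 133 ± 16 to 256 ± 19.9 (adjusted p = 0.044). Tgif1 (0.39, adjusted p = 0.075) and Pmepa1 (0.65, adjusted p = 0.14) missed the threshold. The mean log2 change of the list was 0.18 ± 0.07 (SE over genes), with 19 of 26 genes positive (camera adjusted p = 0.0017; adjusted p = 0.53 with an estimated correlation). The Fstl3 call ended without 0 ng replicate 2 or 50 ng replicate 2 (adjusted p up to 0.063). The Smad7 call ended in 13 of 24 alternatives, among them those without any 1 of the 6 dpp arrays or of the 0 ng arrays of 15 dpp, where its adjusted p reached 0.25.

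Of the 31 measured components of the activin, inhibin and TGF-beta pathways, Fstl3 and Inha rose, and adjusted over the list alone 2 rose and 2 fell. Inha, the inhibin alpha subunit, rose by 0.53 ± 0.11, from 1389 ± 7.2 to 2034 ± 350 (adjusted p = 0.035), a call that ended in 9 of 24 alternatives, including those without either 0 ng array of either age or without 50 ng replicate 2 (adjusted p up to 0.23). The type II receptor gene of anti-Muellerian hormone, Amhr2 (-0.56, adjusted p = 0.065), and the type I receptor gene Tgfbr1 (-0.32, adjusted p = 0.069) missed the threshold. The list did not pass (camera adjusted p = 0.91); its mean was 0.02 while its median was -0.01 and the test pointed downward. Of the genes named throughout, 9 did not pass at 50 ng: Inhba (-0.01), Inhbb (-0.20), Fst (-0.01), Smad2 (0.18), Smad3 (-0.31), Skil (0.23), Ccnd2 (0.70, adjusted p = 0.40), Gja1 (0.35, adjusted p = 0.54) and Amh (0.43). The changes of Ccnd2 were positive in 7 of 7 probe sets and those of Gja1 in 6 of 6. Serpina5, Ccnd2 and Gja1 were recalled as genes of interest to the study, so their inclusion is not independent evidence.

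The 20 measured cholesterol synthesis genes had a mean change of -0.27 ± 0.04 at 50 ng, with 19 negative (camera adjusted p = 8.4e-07; adjusted p = 0.53 with an estimated correlation). Of single genes 1 fell, and 5 fell when adjusted over the list alone. Insig1, an endoplasmic reticulum protein that restrains sterol synthesis, fell by 0.66 ± 0.14, from 312 ± 52 to 193 ± 18.8 (adjusted p = 0.046). Hmgcs1 (-0.44, adjusted p = 0.051), Msmo1 (-0.46, adjusted p = 0.054) and Sc5d (-0.38, adjusted p = 0.059) missed the threshold. Between arrays of the same replicate number, the mean change of the list was -0.26 and -0.28, though the labels do not say what a number marks. The mean of the list was -0.16 without 0 ng replicate 1 and -0.15 without 50 ng replicate 2, and the Insig1 call ended without any 1 of the 6 dpp arrays or of the 0 ng arrays of 15 dpp (adjusted p up to 0.30).

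Junction genes that passed at 50 ng were lower, and maturation genes went both ways. Cldn11, a claudin of the Sertoli cell tight junction, fell by 0.55 ± 0.10, from 2016 ± 224 to 1328 ± 175 (adjusted p = 0.017), and Cgn, which encodes cingulin, by 0.66 ± 0.14 (adjusted p = 0.042), while Espn (-0.47, adjusted p = 0.16) missed the threshold. Of 28 measured tight and adherens junction genes these 2 fell and none rose; adjusted over the list alone, 5 fell and 1 rose. The list's mean was -0.08 ± 0.05 (camera adjusted p = 0.0061; adjusted p = 0.53 with an estimated correlation), and without 0 ng replicate 1 it missed the threshold (mean -0.05, adjusted p = 0.081). Of 21 Sertoli cell maturation genes, Serpina5 rose and Cldn11 and the cystatin gene Cst9 (-0.72 ± 0.15, adjusted p = 0.038) fell; adjusted over the list alone, 2 rose and 7 fell. That list did not pass camera (mean -0.04, median 0.01, test downward, adjusted p = 0.21). Without activin, Serpina5 signals were 298 and 269 at 6 dpp and 159 and 130 at 15 dpp. Its rise with 50 ng was thus not towards the level of the later age. Those of Cldn11 were 2174.5 and 1858 at 6 dpp and 1603 and 1757 at 15 dpp. The calls of Cldn11 (adjusted p up to 0.16), Cgn (up to 0.26) and Cst9 (up to 0.17) ended without either 0 ng replicate or without 50 ng replicate 2, among others.

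In other lists at 50 ng, the Sertoli cell transcription factor gene Gata4 rose by 0.45 ± 0.10 (adjusted p = 0.048) and Aard fell by 0.36 ± 0.07 (adjusted p = 0.026). Stra6, the receptor for retinol-binding protein, rose by 0.82 ± 0.14, from 151 ± 30.1 to 274 ± 4.1 (adjusted p = 0.017), and Mcm3, a subunit of the replicative helicase, by 0.45 ± 0.10 (adjusted p = 0.044). Adjusted over each list alone, 2 Sertoli cell identity genes rose and 3 fell, 2 retinoid genes rose, 1 cell division gene rose, 2 G1 cell cycle regulators rose, 1 matrix gene rose and 1 fell, and 1 BMP-responsive and 1 immediate early gene fell. None of these lists passed camera, with adjusted p values of 0.27 for Sertoli cell identity, 0.97 for retinoid genes and 0.11 for cell division. Cell division genes passed without 50 ng replicate 2, at 0.15 (adjusted p = 0.00097), and matrix genes without 50 ng replicate 1, at 0.086 (adjusted p = 0.046). The mean of the retinoid list was 0.04 and its median -0.04. Without 50 ng replicate 2 the calls of Gata4, Aard, Stra6 and Mcm3 ended, with adjusted p values up to 0.27 for Gata4 over all alternatives. The 6 lists of other cell types had mean changes between -0.04 and 0.13, none past the threshold. Without 50 ng replicate 2, fibroblast and interstitial genes passed at -0.14 (adjusted p = 0.0084), and without 0 ng replicate 1 peritubular myoid and smooth muscle genes passed at 0.21 (adjusted p = 0.011). Hsd17b3, which stands in the Leydig cell list, was the 1 gene of them that passed, and adjusted over the list alone 1 Leydig cell gene rose and 1 fell.

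At 5 ng and 6 dpp, all genes called at 50 ng except E2f5 missed the threshold. Hsd17b1 had a log2 change of 0.83 ± 0.17 with a signal of 142 ± 25.8 (adjusted p = 0.21), Inha 0.49 ± 0.11 with 1919 ± 160.4 (adjusted p = 0.21), and Serpina5 0.46 ± 0.15 with 394 ± 26 (adjusted p = 0.38). Smad7 had 0.55 ± 0.19 (adjusted p = 0.41) and Stra6 0.66 ± 0.14 (adjusted p = 0.21). Both doses were compared with the same 0 ng arrays.

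At 5 ng, 1 gene passed: E2f5, a transcription factor of the E2F family, at 2.49 ± 0.28, from 96.2 ± 20.9 to 614 ± 209 (adjusted p = 0.015). This came from 1 of its 3 probe sets; the other two changed by -0.29 and -0.02 at signals of 159 and 167. The E2f5 call ended in 9 of 24 alternatives, among them those without 0 ng replicate 2, without 5 ng replicate 2 and without either 0 ng array of 15 dpp, with an adjusted p of up to 0.28. The next smallest p values belonged to Adam2 (0.88), Krtap12-1 (-1.16), Pik3cd (0.89) and Adgrg1 (0.54), which all missed the threshold (adjusted p = 0.21 each). Signals of Adam2 were 1.92 and 18.0, and that of Krtap12-1 was 16.1 at 5 ng, all under the filter's 18.4, and with a pseudocount of 1 Adam2 passed (adjusted p = 0.013). A replicate block within each age, chosen after seeing the data, gave 80 genes, with 1797 at an unadjusted p under 0.05. In the fit as reported, 1198 genes had an unadjusted p under 0.05. Of the genes named throughout, none passed; Inhba (0.12), Inhbb (0.05), Fst (0.02), Smad2 (-0.02), Smad3 (-0.04), Skil (-0.02), Ccnd2 (0.40), Gja1 (0.21) and Amh (0.73) complete the set.

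Whole lists shifted at 5 ng at 6 dpp by small amounts. Extracellular matrix genes had a mean of 0.13 ± 0.03, with 33 of 41 positive (camera adjusted p = 1.9e-05; adjusted p = 0.52 with an estimated correlation), led by the collagen gene Col1a1 (0.54, adjusted p = 0.27) and the perlecan gene Hspg2 (0.57, adjusted p = 0.29). Cholesterol synthesis genes had a mean of -0.21 ± 0.05, with 16 of 20 negative (camera adjusted p = 7.4e-05; adjusted p = 0.62 with an estimated correlation), and adjusted over the list alone 7 fell. The cholesterol mean was -0.10 without 0 ng replicate 1 (adjusted p = 0.081), -0.33 without 0 ng replicate 2 and -0.12 without 5 ng replicate 2. SMAD2/3 target genes had a mean of 0.09 ± 0.04 (camera adjusted p = 0.026; adjusted p = 0.62 with an estimated correlation). Germ cell markers had a mean of -0.10 ± 0.03 (camera adjusted p = 0.028; adjusted p = 0.82 with an estimated correlation). The SMAD2/3 list missed without quantile normalisation, with array medians subtracted and with the filter at the 60th percentile. It also missed without 0 ng replicate 2 (mean 0.06) and without 5 ng replicate 1 (mean 0.08). The germ cell list missed without quantile normalisation, with array medians subtracted, with a pseudocount of 64 and without the filter. It also missed without 0 ng replicate 2 (mean -0.10) and without 5 ng replicate 2 (mean -0.06). Adjusted over the list alone, 1 gene rose in each of the pathway, Sertoli cell identity, retinoid, Leydig and fibroblast lists.

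Between 50 and 5 ng, 5 genes differed, 3 higher and 2 lower at 50 ng. Pmm1, a phosphomannomutase gene, was higher by 0.82 ± 0.08, from 316 ± 4.3 to 571 ± 36 (adjusted p = 0.0021), as were Uroc1 (1.64), whose signal was 6.68 at 5 ng and whose change ran from 0.75 to 2.87 over the alternatives, and Crcp (0.73). The ribosomal protein gene Rpl39 (-1.13) and the transcriptional coregulator gene Cited1 (-0.61, from 823 ± 38 to 542 ± 1.2) were lower; these 4 had an adjusted p of 0.046. Hsd17b1 (1.07, adjusted p = 0.061), Serpina5 (0.81, adjusted p = 0.080) and Fstl3 (0.84, adjusted p = 0.089) missed the threshold. The other genes named throughout did not pass, with changes from -0.30 for Amh to 0.33 for Smad7, and 1159 genes had an unadjusted p under 0.05. Leaving out any 1 of the arrays except those of 15 dpp with 5 ng and 50 ng replicate 2 gave 0 to 2 genes, with 0 without 5 ng replicate 1, where Pmm1 also missed the threshold (adjusted p = 0.069). The calls of the other 4 genes ended in 10 to 15 alternatives each.

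Between the doses, cell division genes were higher at 50 ng by a mean of 0.10 ± 0.02, with 40 of 51 positive (camera adjusted p = 0.0065; adjusted p = 0.81 with an estimated correlation). Matrix genes were lower, with a mean of -0.12 ± 0.03 (camera adjusted p = 0.00023; adjusted p = 0.53 with an estimated correlation), as were Sertoli cell identity genes with -0.11 ± 0.04 (camera adjusted p = 0.019; adjusted p = 0.47 with an estimated correlation) and junction genes with -0.09 ± 0.04 (camera adjusted p = 0.0066; adjusted p = 0.53 with an estimated correlation). Fibroblast and interstitial genes, which share 6 genes with the matrix list, had a mean of -0.09 with 11 of 15 negative and missed the threshold (camera adjusted p = 0.052). They passed without 50 ng replicate 2, at -0.18 (adjusted p = 0.00013), and also without 5 ng replicate 1, either 6 dpp 0 ng array, 15 dpp 0 ng replicate 2 or either 15 dpp 5 ng array (adjusted p from 0.026 to 0.049). Cholesterol synthesis genes passed without 5 ng replicate 2, at -0.15, or without 50 ng replicate 1, at -0.18, and Sertoli cell maturation genes without 15 dpp 5 ng replicate 1, at -0.07 (adjusted p = 0.042). Adjusted over the list alone, 1 SMAD2/3 target gene, 1 pathway component and 1 maturation gene were higher, and 2 maturation genes and 1 junction gene lower. Without 50 ng replicate 1, the cell division (mean 0.03, adjusted p = 0.64), matrix (mean -0.05, adjusted p = 0.40) and identity lists (mean -0.05, adjusted p = 0.25) missed the threshold, and without 50 ng replicate 2 their means were 0.18, -0.18 and -0.17. The threshold was also missed by cell division without 5 ng replicate 2 (mean 0.08), and by the identity (mean -0.12) and junction lists (mean -0.06) without 5 ng replicate 1. The identity list also missed without quantile normalisation, with array medians subtracted and without the variance trend. The junction list also missed with array medians subtracted and with every probe set.

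Across the 12405 genes, the changes at 5 and 50 ng at 6 dpp correlated at r = 0.58, with 70.2% of genes of the same sign; genes are not independent replicates. Unchanged groups that shared a simulated control group gave r = 0.50 and 66.7%. The simulation did not draw on the 0 ng arrays themselves or on ties between arrays of the same number. The covariance was 0.026 against 0.013 simulated, a difference of 0.013. The doses shared 1 call, E2f5, which rested on 1 probe set. Independent lists would share 0.0078, but these lists share the 0 ng arrays, so this overlap does not show agreement of the doses. Part of the excess of the correlation and covariance over the simulation may come from the shared controls, which could not be split. The changes at 5 ng at 6 and 15 dpp, which share no array, correlated at r = 0.025 with 50.8% of the same sign.

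At 15 dpp, 5 ng activin changed no single gene past the threshold in limma as reported (0 genes, smallest adjusted p = 0.22). A replicate block within each age, chosen after seeing the data, gave 20 genes. With that block, 972 genes had an unadjusted p under 0.05. In the fit as reported 605 did, where chance gives 620.25. Serpina5 had a log2 change of 0.62 ± 0.15, from 145 ± 20.5 to 241 ± 67 (adjusted p = 0.51), and Hsd17b1 0.59 ± 0.17 at signals of 15.5 and 31.0 (adjusted p = 0.60). The smallest p values belonged to Cdk14 (0.57), Vamp3 (-0.39), Abcb10 (0.68), Ror1 (0.73) and Bok (0.53), each with an adjusted p of 0.22. Of the other genes named throughout, Inha had 0.32 (adjusted p = 0.82), Skil 0.27, Gja1 0.29, Amh 0.20, Smad2 0.17, Smad3 0.10, Smad7 -0.02, Inhbb -0.02, Inhba -0.09, Fst -0.11 and Ccnd2 -0.12. Without 5 ng replicate 2, 1 gene passed in limma.

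Lists of matrix and contractile genes were slightly higher with 5 ng at 15 dpp. Peritubular myoid and smooth muscle genes had a mean of 0.19 ± 0.06, with 12 of 14 positive (camera adjusted p = 0.00017; adjusted p = 0.47 with an estimated correlation), and adjusted over the list alone 2 rose. The smallest p belonged to Lmod1 (0.81, adjusted p = 0.51), at a signal of 5.27 without activin, and Tagln (0.31, adjusted p = 0.66). Matrix genes had a mean of 0.10 ± 0.02, with 34 of 41 positive (camera adjusted p = 8.8e-05; adjusted p = 0.53 with an estimated correlation), led by the laminin gene Lamb1 (0.40, adjusted p = 0.27), of which 1 of 3 probe sets had that sign. SMAD2/3 target genes had a mean of 0.09 ± 0.03, with 19 of 26 positive (camera adjusted p = 0.0047; adjusted p = 0.53 with an estimated correlation), led by Ccn2 (0.30, adjusted p = 0.30). The SMAD2/3 list missed the threshold without 0 ng replicate 1 (mean 0.0029, adjusted p = 0.58) and without 5 ng replicate 2 (mean 0.01, adjusted p = 0.53), and the matrix list without 5 ng replicate 2 (adjusted p = 0.091). The SMAD2/3 mean was 0.18 without 0 ng replicate 2 and 0.17 without 5 ng replicate 1. Adjusted over the list alone, 1 gene each rose in the SMAD2/3, matrix and maturation lists. Glycolysis genes had a mean of -0.02 that passed in opposite directions when either 5 ng array was left out, at 0.27 without 5 ng replicate 1 and -0.30 without 5 ng replicate 2, as did 2 other lists. Immediate early genes had 0.18 and -0.16, and germ cell markers -0.092 and 0.087.

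The 5 ng response was compared directly between the ages. No single gene differed in limma as reported (0 genes, smallest adjusted p = 0.50), whereas the replicate block within each age gave 10 genes. With that block, 1339 genes had an unadjusted p under 0.05, and in the fit as reported 834 did. The smallest p values belonged to Dbi (0.41), Tnks2 (-0.60), Dync1li1 (-1.06), Slc22a17 (-0.80) and Srsf1 (0.43), each with an adjusted p of 0.50. The difference was -0.57 ± 0.27 for Smad7 (adjusted p = 0.74), -0.17 for Inha and 0.16 for Serpina5, and none of the genes named throughout passed. Cholesterol synthesis genes differed as a list: their response was more positive at 15 dpp by a mean of 0.26 ± 0.06, with 17 of 20 positive (camera adjusted p = 0.00016; adjusted p = 0.65 with an estimated correlation). Msmo1 had a difference of 0.49 (adjusted p = 0.70). The mean was 0.14 without 6 dpp 0 ng replicate 1 and 0.16 without 6 dpp 5 ng replicate 2, and without 15 dpp 5 ng replicate 2 the test of single genes gave 2 genes.

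**Figure D2:**
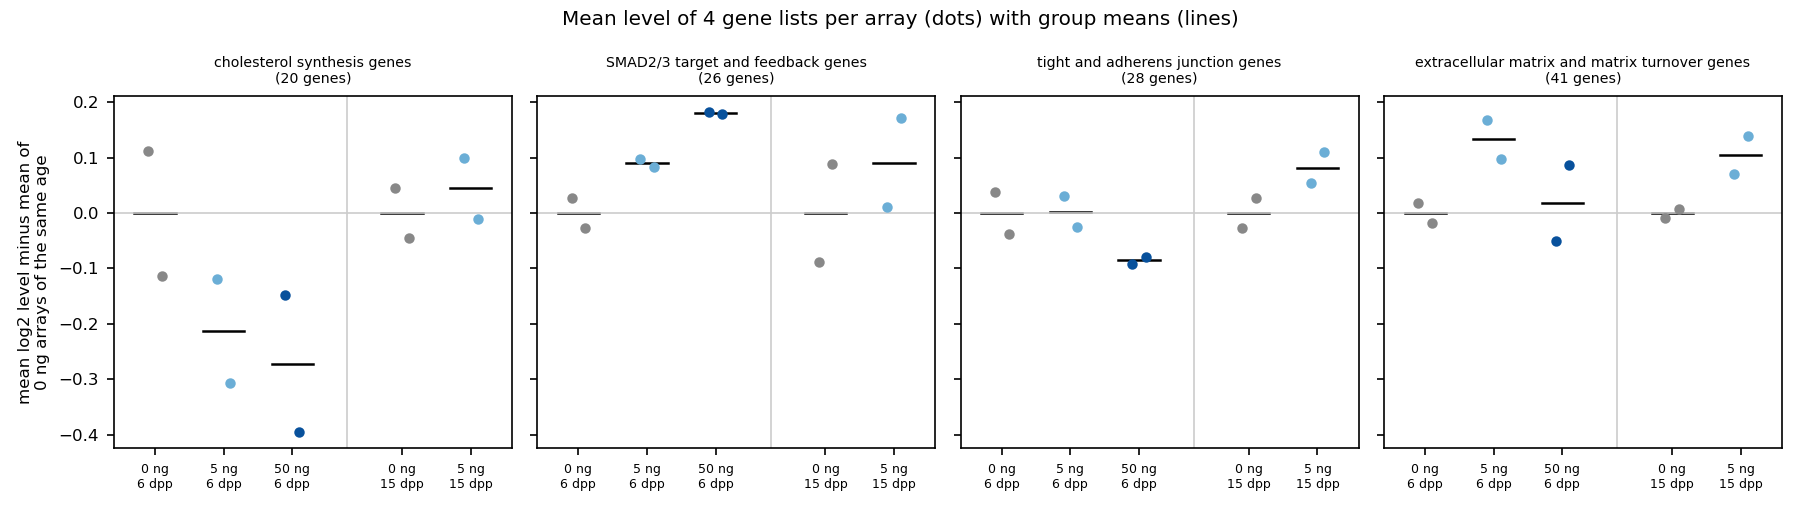
Mean log2 level of 4 gene lists on each array (dots; lines are the means of 2 arrays), relative to the 0 ng arrays of the same age. Cholesterol synthesis genes lay at -0.15 and -0.40 on the 50 ng arrays numbered 1 and 2. On the 0 ng arrays of 6 dpp they lay at 0.11 and -0.11. These groups did not overlap but their arrays were spread widely, and the array numbered 2 lay lower at each dose of 6 dpp. SMAD2/3 target genes lay at 0.18 on both 50 ng arrays.

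Without activin, cells of 15 dpp expressed genes of meiotic germ cells far above those of 6 dpp, and genes of the matrix, of immature Sertoli cells and of cholesterol synthesis far below. Ldhc, the lactate dehydrogenase of male germ cells, was higher by 7.06 ± 0.20 on the log2 scale, from 14.7 ± 10.5 to 3982 ± 92 (adjusted p = 1.3e-10), and Sycp3, a component of the synaptonemal complex, by 4.44 ± 0.10, from 135 ± 22 to 3203 ± 139.7 (adjusted p = 4.3e-11). Mfap4, a microfibril-associated protein gene, was lower, with a log2 change of -4.59 ± 0.23, from 991 ± 95 to 24.9 ± 2.1 (adjusted p = 7.6e-09), and Dlk1 with -3.87 ± 0.16, from 659 ± 66 to 29.6 ± 7.4 (adjusted p = 1.2e-09). On the scale used, the other largest increases were Fabp9 (6.42), Spata4 (5.79), Meig1 (5.60), Ybx2 (5.57), Ly6k (5.53), Pdcl2 (5.48) and Rsph1 (5.39). Most of these genes had signals near or under the filter's 18.4 at 6 dpp, so that their sizes and order depended on the pseudocount. Over the alternatives, Ldhc ran from 5.95 to 8.14, Fabp9 from 4.58 to 9.12, Spata4 from 4.26 to 7.41, Ybx2 from 3.88 to 7.53 and Pdcl2 from 3.72 to 7.88. The other largest decreases were the glutamate transporter gene Slc1a6 (-3.89), Hsd17b3 (-3.75, ranging from -5.02 to -2.43), Ptprz1 (-3.69), the neurokinin receptor gene Tacr3 (-3.68), Prss23 (-3.66) and the desmoplakin gene Dsp (-3.65). In all, 7093 genes (57.2%) passed, 3574 higher and 3519 lower at 15 dpp, of which 1100 and 1146 differed by more than 2-fold.

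Markers of other cell types moved with age in both directions. Of 34 measured germ cell markers, 30 were higher and 4 lower at 15 dpp, with a mean of 2.15 ± 0.31 (camera adjusted p = 5.4e-12; adjusted p = 0.47 with an estimated correlation), led by Sycp3, Sycp2 (3.91), Ldhc and Dazl (2.12, from 574 ± 17 to 2511 ± 93). Of 13 macrophage markers 10 were higher and none lower, with a mean of 0.83 ± 0.12 (camera adjusted p = 0.025; adjusted p = 0.62 with an estimated correlation), among them the mannose receptor gene Mrc1 (1.52). Fibroblast and interstitial genes were lower, 12 of 15, with a mean of -1.70 ± 0.22 (camera adjusted p = 8.4e-07; adjusted p = 0.47 with an estimated correlation), as were peritubular myoid and smooth muscle genes, 12 of 14, with a mean of -1.19 ± 0.22 (camera adjusted p = 6.0e-05; adjusted p = 0.47 with an estimated correlation), among them Tagln (-3.48) and Acta2 (-1.12). Of 8 Leydig cell markers, 6 were lower, including Hsd3b1 (-2.21), and 1, the cholesterol transport gene Star (1.76), was higher, with a mean of -1.38 ± 0.60 (camera adjusted p = 0.028; adjusted p = 0.47 with an estimated correlation), which missed the threshold with a pseudocount of 1, with the filter at the 60th percentile and with every probe set (adjusted p up to 0.12). Endothelial markers did not pass (mean 0.02, median -0.23, adjusted p = 0.96); Robo4 (2.05) was higher and Cdh5 (-0.87), Eng (-0.58) and Egfl7 (-0.62) lower. The Cdh5 call ended without 0 ng replicate 2 of 6 dpp or replicate 1 of 15 dpp (adjusted p up to 0.079). The calls of Eng and Egfl7 ended without 0 ng replicate 1 of 6 dpp or replicate 2 of 15 dpp (adjusted p up to 0.15 and 0.28 over all alternatives). The macrophage list missed the threshold with a replicate block within each age. It also missed without 0 ng replicate 2 of 15 dpp (mean 0.67) and without 0 ng replicate 1 of 6 dpp (mean 0.78). Red blood cell markers had 1 measured gene and were not tested.

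Lists named for Sertoli cells also differed between the ages, alongside the germ cell and fibroblast markers. The fibroblast, peritubular and Leydig lists were lower as well, so lower values here cannot be assigned to Sertoli cells alone. All 17 immature Sertoli cell genes that passed, of 21 measured, were lower at 15 dpp, with a mean of -1.28 ± 0.24 (camera adjusted p = 3.8e-06; adjusted p = 0.42 with an estimated correlation); they included Dlk1, the imprinted transcript Meg3 (-3.59) and the thyroid hormone receptor gene Thra (-1.41). Of 16 Sertoli cell identity genes, 12 were lower and 1 higher, with a mean of -0.79 ± 0.18 (camera adjusted p = 0.0014; adjusted p = 0.42 with an estimated correlation), led by Tcf21 (-1.96), the desert hedgehog gene Dhh (-1.26), Dmrt1 (-1.55) and Lhx9 (-2.10). Tcf21 is 1 of 2 genes that the identity list shares with the fibroblast and interstitial list, whose mean was -1.70. Of 21 maturation genes, 10 were higher and 4 lower, including the aquaporin gene Aqp8 (3.04, from 17.9 to 273), the transcription factor gene Gata1 (1.99), Eppin (2.24) and Tsx (2.20), and the list missed the threshold (mean 0.59 ± 0.25, camera adjusted p = 0.10). Adjusted over the list alone, 11 maturation genes were higher, and the counts of the immature and identity lists were those given.

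Activin ligands and targets were lower at 15 dpp. Inhba and Inhbb, the activin beta subunits, had log2 changes of -2.28 ± 0.12, from 556 ± 82 to 98.1 ± 4.0 (adjusted p = 1.3e-08), and -2.08 ± 0.09, from 1851 ± 39 to 422 ± 64 (adjusted p = 2.2e-09). Inha had -0.98, Smad7 -0.85, Skil -0.77, Serpina5 -0.88 and Amh -1.40, at signals of 40.6 and 5.28, and all passed. The Amh change ran from -2.93 to -0.59 over the alternatives. Gja1, the gap junction gene of connexin 43, had -0.89 (adjusted p = 0.0048), a call that ended without 0 ng replicate 1 of 15 dpp (adjusted p = 0.074). Fst (-0.16), Smad2 (-0.24, adjusted p = 0.092), Smad3 (-0.10) and Ccnd2 (0.39) did not pass. Of 26 SMAD2/3 target genes 17 were lower and 2 higher, with a mean of -1.04 ± 0.23 (camera adjusted p = 0.00011; adjusted p = 0.47 with an estimated correlation), led by Ccn2 (-2.58) and Ccn1 (-2.84). Of 31 pathway components 18 were lower and 3 higher, with a mean of -0.63 ± 0.17 (camera adjusted p = 0.0016; adjusted p = 0.47 with an estimated correlation), among them Tgfb2 (-2.78) and Tgfbr2 (-1.52). BMP-responsive genes did not pass (5 lower and 1 higher of 8, mean -0.53, adjusted p = 0.18), with Id4 higher (2.54) and Id1 lower (-1.34).

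Structural and metabolic genes followed. Of 41 matrix genes 38 were lower and 2 higher at 15 dpp, with a mean of -1.72 ± 0.15 (camera adjusted p = 6.3e-16; adjusted p = 0.42 with an estimated correlation), including Lamb1 (-2.63), Bgn (-2.70) and Col1a2 (-2.52). All 20 measured cholesterol synthesis genes were lower, with a mean of -1.47 ± 0.12 (camera adjusted p = 1.1e-08; adjusted p = 0.53 with an estimated correlation), among them Cyp51 (-2.76), Msmo1 (-2.23) and the squalene epoxidase gene Sqle (-2.06). Of 18 glycolysis and lactate export genes 10 were higher and none lower, with a mean of 0.73 ± 0.21 (camera adjusted p = 0.034; adjusted p = 0.82 with an estimated correlation), led by the glucose transporter gene Slc2a3 (3.25) and the monocarboxylate transporter gene Slc16a1 (0.95); adjusted over the list alone 11 were higher. That list missed the threshold with the filter at the 60th percentile, without the variance trend and with a replicate block within each age. It also missed without 0 ng replicate 2 of 15 dpp (mean 0.46) and without 0 ng replicate 2 of 6 dpp (mean 0.66). Of 51 cell division genes 29 were higher and 8 lower, with a mean of 0.56 ± 0.12 (camera adjusted p = 0.0019; adjusted p = 0.78 with an estimated correlation), among them Cdc20 (2.28), Bub1 (2.75) and Top2a (1.72). Germ cell markers were higher on the same arrays, so the higher glycolysis and cell division lists cannot be assigned to Sertoli cells alone.

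The remaining lists did not pass between the ages. G1 cell cycle regulators had 5 higher and 6 lower of 19 (mean -0.02, median 0.07, adjusted p = 0.97), with Ccnd3 (-1.41) and Cdk6 (-1.96) lower. Junction genes had 6 higher and 15 lower of 28 (mean -0.30, adjusted p = 0.15), among them the occludin gene Ocln (-1.24). Retinoid genes had 4 higher and 3 lower of 14 (mean 0.10, adjusted p = 0.97), with Aldh1a1 (-0.97) lower. Immediate early and stress genes had 8 higher and 18 lower of 34 (mean -0.34, adjusted p = 0.24), with Dusp1 (-2.17) and Egr1 (-1.95) lower. Cytokine and inflammation genes had 2 higher and 8 lower of 18, or 9 lower adjusted over the list alone (mean -0.45, adjusted p = 0.095), with Cx3cl1 (-2.20) lower. That list passed without 0 ng replicate 2 of 6 dpp, at -0.58 (adjusted p = 0.036), or of 15 dpp, at -0.53 (adjusted p = 0.028). With an estimated correlation none of the 126 list tests passed, while fry passed 16 lists between the ages and 0 in each other comparison.

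**Figure D3:**
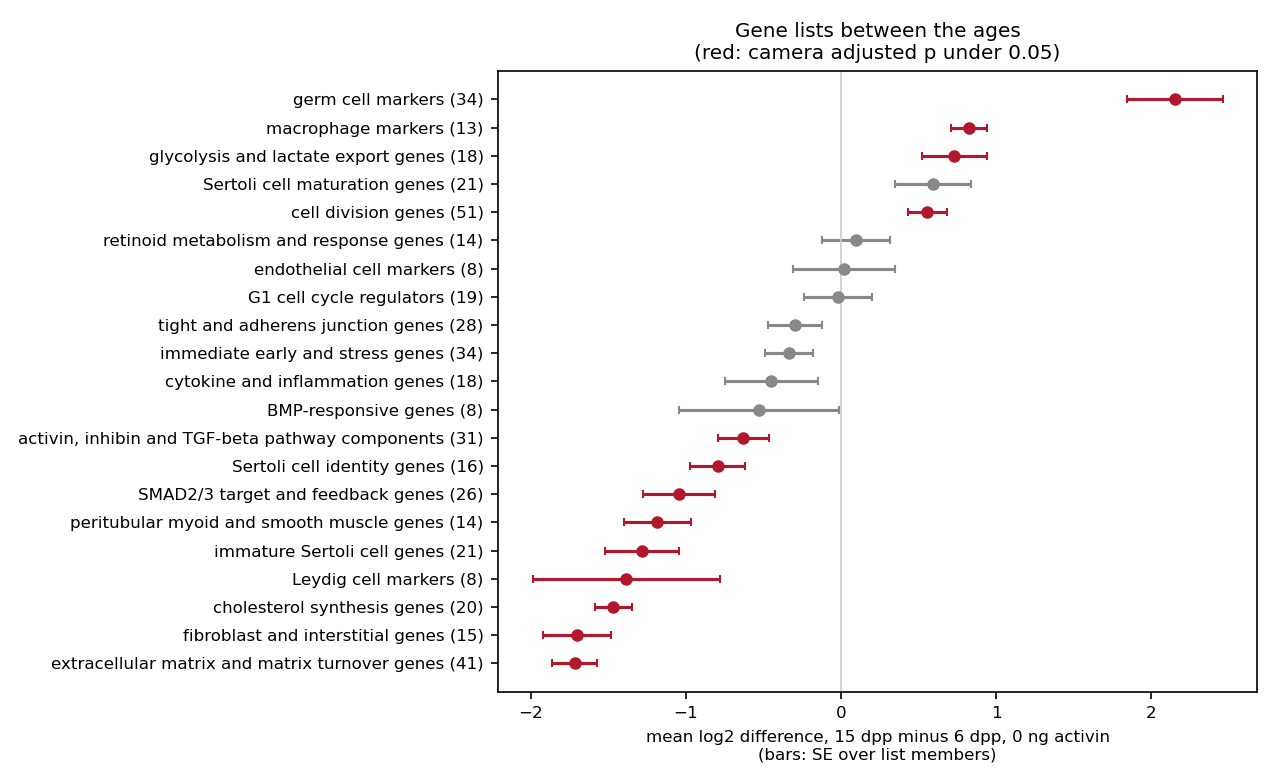
Mean log2 difference between 15 and 6 dpp without activin for 21 gene lists (points; bars are the SE over the list's genes; the number of measured genes is in parentheses), with lists that passed camera in red. Germ cell markers stood highest at 2.15 and matrix genes lowest at -1.72; no list passed with an estimated correlation.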

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

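All tests of explanations in this part were chosen after the results they bear on were seen. The response of cholesterol synthesis genes to 5 ng activin differed between the ages by a mean of 0.2575 on the log2 scale in the test of the difference itself (camera adjusted p = 0.00016), and with an estimated correlation it did not pass (adjusted p = 0.65). Probe sets without a single gene name, which the comparisons of genes leave out, also passed: 1 at 5 ng and 18 at 50 ng at 6 dpp, when all 27022 probe sets were tested.

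The response to 50 ng activin at 6 dpp was set against 3 technical explanations. A changed share of other cell types would move a marker list by about as much as the called genes, whose median size was 0.61. The largest mean plus 2 SE among the 6 lists (Leydig cell markers) was 0.467. That SE is over genes and holds no spread between arrays, so 0.467 is not a firm limit. The peritubular mean was 0.21 without 0 ng replicate 1, and the fibroblast mean was -0.14 without 50 ng replicate 2. These values lay below 0.61 in size but do not exclude this explanation. Under both other scalings, at least 99.4% of the called genes kept their sign with an unadjusted p under 0.05. These genes had been called at a stricter threshold, so this could hardly fail and does not decide on a difference in signal distribution. In limma, 175 genes passed without quantile normalisation and 98 with array medians subtracted, of which 95 were among the 179. A difference in RNA integrity was argued against by 3' to 5' control ratios that differed by at most 1.01 times between 0 and 50 ng. A direct response of Sertoli cells to activin stays open as a hypothesis, as does any difference between preparations, which 2 arrays per group of unstated origin do not separate from the dose.

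The difference between 15 and 6 dpp may reflect a change in cell composition as well as in Sertoli cells. A lower Sertoli cell share with all other types raised alike was argued against, since fibroblast genes lay below 0 even at their mean plus 2 SE over genes, -1.26. Relative to 6 dpp at 0 ng, their means were -1.66 and -1.74 on the 0 ng arrays of 15 dpp. RNA integrity was argued against as a cause by 3' to 5' control ratios that differed by at most 1.11 times. More germ cells at 15 dpp remained a candidate explanation for the germ cell part. The mean of their markers minus 2 SE over genes was 1.53, from a list that shared no gene with the others. Signals of abundant members were high at 15 dpp (Ldhc 3982, Sycp3 3203, Dazl 2511). The list holds genes of meiosis such as Sycp3, so it cannot tell a larger number of germ cells from a later stage of them. The labels name no sorting step, and maturation of the Sertoli cells is open and was not tested apart from composition. A lower activin subunit, matrix or immature Sertoli cell signal at 15 dpp therefore cannot be assigned to Sertoli cells alone. The same holds for the higher glycolysis and cell division signals.

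E2f5 at 5 ng activin and 6 dpp rested on 1 probe set. The other two probe sets of the gene, at signals of 159 and 167, changed by at most 0.29 in size, the larger change being -0.29, while the called one changed by 2.49. A signal of that probe set alone, such as a transcript variant or cross-hybridisation, is a candidate explanation, and a change of the whole E2f5 transcript was argued against.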

How the results depend on the processing

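The fit with a replicate block within each age and the comparison of lists between arrays of the same number were chosen after seeing the data; all other alternatives were planned. Counts are in the order 5 ng at 6 dpp, 50 ng at 6 dpp, 50 against 5 ng, 5 ng at 15 dpp, age, and difference of the response, with 1, 179, 5, 0, 7093 and 0 as reported. Over the fits that each left out 1 array, in which the lone array was assumed to vary like the other groups, they ranged over 0 to 2, 17 to 168, 0 to 7, 0 to 1, 5999 to 7105 and 0 to 2. The 179 genes kept their sign in every fit that measured them. Subtracting array medians gave 2, 98 and 8 genes in the first 3 comparisons, a pseudocount of 1 gave 2 at 5 ng at 6 dpp and 1 at 15 dpp, and a pseudocount of 64 gave 11 between the doses. Without the filter there were 0, 110 and 1 genes, with the mean of all probe sets 0 and 18 for 5 ng at 6 dpp and between the doses, and with every probe set 6, 3 and, for age, 12996, where more features were tested. Without the variance trend there were 0, 46 and 0 genes, with only the arrays of the comparison 0, 94 and 0, on 2 residual degrees of freedom, and with robust moderation 0 at 5 ng at 6 dpp. Adjusting over all 6 comparisons together, which lets the age comparison set the threshold, gave 164, 425, 196, 82 and, for the difference, 75 genes. Apart from those constructions the cause was not tested.

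The replicate numbers are shared between groups, and the labels do not say what a number marks. Deviations of arrays with the same number correlated at 0.16 to 0.20 within an age and at -0.051 to 0.029 across ages, a hint from the data. At 15 dpp, glycolysis genes lay at 0.46 and 0.43 on the 0 and 5 ng arrays numbered 1 and at 0.997 and 0.998 on those numbered 2, relative to 6 dpp at 0 ng. Immediate early genes lay at -0.48 and -0.50 against -0.19 and -0.16, and germ cell markers at 2.22 and 2.24 against 2.08 and 2.06, so leaving out 1 array of 15 dpp sets unlike numbers against each other. At 6 dpp, cholesterol synthesis genes lay at 0.11, -0.12 and -0.15 on the 0, 5 and 50 ng arrays numbered 1. On those numbered 2 they lay at -0.11, -0.31 and -0.40, so leaving out 1 of these arrays does the same there. Paired by number, the mean change was 0.099 and 0.083 for SMAD2/3 target genes with 5 ng at 15 dpp and -0.26 and -0.28 for cholesterol synthesis genes with 50 ng at 6 dpp. For matrix genes between the doses it was -0.22 and -0.012, so pairing did not even out every list. A replicate block gave 1, 230, 8, 0, 7252 and 0 genes, and a replicate block within each age 80, 600, 141, 20, 7091 and 10. In the latter, Ccnd2 turned with age to -0.16; the cause was not tested.

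The correlation of the 5 and 50 ng changes ranged from 0.44 to 0.69 without single arrays, and that of the 5 ng changes at 6 and 15 dpp from -0.022 to 0.061, reaching -0.027 with every probe set; the cause was not tested. Of 28 list results that passed, 548 of 615 alternatives passed in the same direction and 67 missed. The misses include all 28 results with an estimated correlation. The other alternatives kept the preset correlation of 0.01, so their passes do not bear on that choice. At 15 dpp with 5 ng, lists without a call passed when 1 array was left out, in a direction opposite to camera's with all arrays, which was down for glycolysis (mean -0.02) and immediate early genes (mean 0.0069) and up for germ cell markers (mean -0.0024): glycolysis genes at 0.25 without 0 ng replicate 2 and 0.267 without 5 ng replicate 1 (range -0.299 to 0.267), immediate early genes at 0.152 and 0.178 without the same arrays (range -0.164 to 0.178), and germ cell markers at -0.092 without 5 ng replicate 1 (range -0.092 to 0.0871). The levels by number above go with these calls. Over all comparisons, lists without a call passed in camera's direction in 64 alternatives and against it in 5; the cause was not tested for the others. In the difference of the response, lists that gained a call without single arrays were glycolysis genes (-0.34 without 15 dpp 0 ng replicate 1, -0.35 without 15 dpp 5 ng replicate 2), germ cell markers (0.17 and 0.19 without the same arrays), immediate early genes (0.22 without 15 dpp 0 ng replicate 2, 0.24 without 15 dpp 5 ng replicate 1), junction genes (0.11 without either, 0.12 without 6 dpp 0 ng replicate 2), peritubular genes (0.29 without 6 dpp 0 ng replicate 2) and BMP-responsive genes (0.24 without 15 dpp 5 ng replicate 1). With 5 ng at 15 dpp, junction genes (0.11) and cell division genes (-0.08) gained a call without 0 ng replicate 2 or 5 ng replicate 1, and retinoid (0.23), BMP-responsive (0.21), cytokine (0.17) and immature Sertoli cell genes (0.13) without 5 ng replicate 1. Of the named genes that passed, 2908 of 3175 alternatives passed in the same direction and 267 missed. Genes with signals near or under the filter's 18.4 have changes limited by background.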

Other observations

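Both tests in this part were chosen after the results were seen, on genes picked by the 50 ng response, so they are hypotheses. The 97 genes raised by 50 ng at 6 dpp had a mean log2 change of 0.18 with 5 ng at 15 dpp, with 77 positive, against 0.75 at 50 ng at 6 dpp. The 82 lowered genes had a mean of -0.05 there, with 50 negative, against -0.61. Together 70.9% kept their sign, and fry's test of the signed set gave p = 0.020; camera with an estimated correlation gave p = 0.0094 for the raised and p = 0.19 for the lowered genes. No array is shared between these comparisons, so cells of 15 dpp may carry part of the same response, mainly among the raised genes. No single gene passed there in the fit as reported. The 50 ng values come from a higher dose and from the comparison that picked the genes, so their size is no measure of age. The median ratio to the 50 ng change was 0.171 for 5 ng at 15 dpp. For 5 ng at 6 dpp, which shares the 0 ng arrays with the 50 ng comparison, it was 0.435. Whether the response is weaker at 15 dpp than at 6 dpp was tested only at 5 ng. No gene passed there in the fit of all 10 arrays as reported. With a replicate block within each age 10 passed, 2 with a positive and 8 with a negative difference.

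Genes raised by activin at 6 dpp tended to be those expressed less at 15 dpp. With the ages compared on the 5 ng arrays, 72.1% of the 179 genes differed in the direction opposite to the 50 ng response: 76 of 97 raised genes were lower at 15 dpp and 53 of 82 lowered genes higher, where 50.5% of all genes were lower. The 5 ng arrays of 6 dpp hold an activin effect of their own, which favours this result. On the 0 ng arrays, which share the 6 dpp controls with the 50 ng comparison and so work against it, 61.5% were opposite. There 66 of 97 raised genes were lower and 44 of 82 lowered genes higher, where 49.8% of all genes were lower. On these arrays the tendency thus lay mainly among the raised genes. A falling activin tone with age is consistent with this, as Inhba and Inhbb were lower at 15 dpp, but a changed mix of cells could give it too, and no test here separated them. Individual genes went both ways: Socs2, chosen as an example after its values were seen, was raised by 50 ng and lower with age (-2.53), whereas Fstl3, chosen in the same way, was raised by 50 ng and higher with age (1.49).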
